A study of Mus musculus with 12 samples.

How the data were processed

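RNA was sequenced from 12 samples that the labels call tumor-associated macrophages, taken from mouse melanomas. The full genotype of the mice is not reported here. Per the labels' protocols treatment began 30 days after tumor induction at a total tumor volume below 100 mm3 and lasted 30 days or until a tumor reached 2 cm3. The 4 groups of 3 samples were Control, CD40 agonist (the antibody FGK4.5, which activates the receptor CD40, at 10 mg/kg every 3 days by intraperitoneal injection for 10 doses), CSF1Ri (PLX6134, read here as an inhibitor of the CSF1 receptor, in chow at 600 mg/kg) and CSF1Ri + CD40 agonist, called the combination here. Each sample pooled at least 3 tumors. Per the labels' protocols tumors were digested with collagenase, red cells were lysed and dead cells were removed over a density medium. No sorting gate for the sequenced cells is given in the sources used here, so markers of other cell types were measured beside the macrophage genes.

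Per the labels' protocols libraries without strand information were made from 50 ng of RNA with a kit for ultra-low input and sequenced as paired 75-bp reads with 6 libraries per lane. Which libraries shared a lane is not given in the sources used here, so lane could not be tested. Per the submitters' processing notes reads were aligned with STAR to mm10 (GRCm38), counted with HTSeq and compared with DESeq2. The deposited files hold something else: per the file headers each has, for every transcript, a length, an effective length, an estimated count and a TPM value. That layout is one that transcript quantifiers write and HTSeq does not, and the quantifier, its version and its annotation are not given in the sources used here. The estimated counts deposited by the authors are not normalized, and of the values above 0 only 8.8% to 10.2% per library are whole numbers, counted without tolerance (a remainder of exactly 0). The TPM values deposited by the authors sum to 1000000 in each library and were used only to identify the unit. Such counts are divided between transcripts that share sequence, so genes with near-identical copies (H2-K1 and its class I neighbours, the Gbp, Klra, Mcpt, Ear and hemoglobin families, and pseudogenes such as Gm9973) are uncertain, as are genes that overlap one on the other strand.

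Each file lists 111462 transcripts, of which 110203 (98.9%) matched a transcript of GENCODE M21 (GRCm38) once version numbers were removed. The unmatched transcripts held 0.378% to 0.436% of the counts per library and were left out. Estimated counts were summed over the transcripts of a gene and rounded to whole numbers, which gave 34989 genes, only 35 of them long non-coding RNA genes. Coordinates given here are gene spans in GENCODE M21 on GRCm38, 1-based, and values cover the exons of a gene's listed transcripts. Library totals ran from 26316328 to 39818657 counts. CPM values are counts scaled to a library of 1000000 after TMM scaling. A floor of 3 counts over the 3 libraries of a group is used where a group had no count. Such floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Labels do not say that the samples of a group came from separate cages or days, so p-values measure the spread between pooled samples.

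All 12 libraries entered one fit with a term per group in edgeR 4.0.16 (R 4.3.3), with TMM scaling, filterByExpr (16027 genes kept) and robust quasi-likelihood F-tests at 8 residual degrees of freedom. Calls are genes with a Benjamini-Hochberg adjusted p below 0.05. The installed version runs the older form of the quasi-likelihood fit by default, and its newer bias-adjusted form was run as an alternative. The comparisons were CD40 agonist, CSF1Ri and the combination against Control, the combination against each single agent, the interaction of both agents (the effect of one agent with the other present minus its effect alone) and any difference among the 4 groups. Standard errors (SE) come from the fit, and SD is the spread between 3 libraries.

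31 gene lists were tested with limma 3.58.1's camera on log2 CPM (prior count 2), with the preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 31 lists of a comparison. The tests were repeated with a correlation estimated from the data, and with fry, which asks whether the genes of a list move one way without comparing them with other genes. The 18 pathway lists were inflammatory cytokines and mediators, chemokines, the NF-kB pathway and its targets, type I interferon response, interferon gamma response, MHC class I presentation, MHC class II presentation, co-stimulation and checkpoint ligands, alternative activation and tissue remodelling, macrophage identity and complement, the CSF1 receptor and CD40 axis, cell cycle, lysosome and lipid handling, glycolysis and hypoxia, phagocytic and Fc receptors, pattern recognition, dissociation and stress, and mitochondrially encoded genes. The 13 lists of other cell types held markers of melanocytes and melanoma, T cells, NK cells, B cells, neutrophils, monocytes, dendritic cells, mast cells and eosinophils, fibroblasts, endothelial cells, keratinocytes, erythroid cells, and muscle and adipocytes. Several monocyte and dendritic cell markers are also expressed by macrophages. Genes named in the text are Csf1r, Csf1, Cd40 and Cd40lg; per comparison up to 8 rises and 8 falls of largest log2 fold change among called genes with a mean of at least 10 CPM, an established symbol and groups whose libraries do not overlap; and per list up to 4 called members of smallest p, or the member of smallest p given as a value. Cd40lg was removed by the filter.

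The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. Those alternatives were DESeq2 1.42.0 size factors in the same fit, DESeq2's own test, no filter, the replicate number as a block, each library left out in turn, the submitters' threshold (log2 change of at least 1.5 and Holm-Sidak p of at most 0.01, with DESeq2), a threshold of at least 1 on the log2 scale, and only the 6 libraries of the compared groups. Chosen after seeing the data were leaving out 2 outlying libraries together, the bias-adjusted quasi-likelihood, limma voom with library weights, and an offset for effective length. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

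The tests were checked on simulated data with the means over all 12 libraries, the spread of the 4-group fit and the depth of each library. Of 16027 genes 200 were changed in the combination libraries. For the combination against Control edgeR called 7 of 67 genes changed 2-fold, 22 of 67 changed 4-fold and 40 of 66 changed 8-fold, with 1 unchanged gene called. DESeq2 called 17, 33 and 47 of these, with 44 unchanged genes called. With the MHC class I list shifted by 0.5 on the log2 scale, camera gave adjusted p = 4.81e-12 with the preset and 0.00288 with an estimated correlation, and called 0 other lists. Simulated genes were drawn independently of each other, so this does not check the preset correlation or the false calls of lists in the real libraries.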

Results

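Macrophage RNA from induced mouse melanomas was compared between 4 groups of 3 libraries, Control, CD40 agonist, CSF1Ri and the combination of both agents. The series is about whether a pair of therapies aimed at myeloid cells act together on inflammation. Estimated counts summed to between 28709482 and 31698533 per library in Control, 26316328 and 33948213 with the CD40 agonist, 26665394 and 32880763 with CSF1Ri and 34168389 and 39818657 with the combination. Lyz2, the lysozyme gene of macrophages, monocytes and neutrophils, stood at 15700 ± 1960 CPM (SD, n = 3) in Control, 14600 ± 2310 with the CD40 agonist, 21500 ± 940 with CSF1Ri and 19000 ± 10400 with the combination. Log2 CPM correlated at 0.874 to 0.934 between libraries, no pair of which held identical values. Combination replicate 2 stood apart from its group, at -105.8 on the second principal component against -32.5 and -55.6 for replicates 1 and 3. CSF1Ri replicate 3 stood apart on the same component (32.7 against -22.2 and -24). The common dispersion corresponded to a coefficient of variation of 61%.

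Csf1r, the receptor that CSF1Ri is read to target (ENSMUSG00000024621, chromosome 18, 61100598 to 61132149), was measured at 859 ± 16.6 CPM in Control, 980 ± 99 with the CD40 agonist, 680 ± 81.1 with CSF1Ri and 839 ± 322 with the combination. No comparison called Csf1r. Its ligand gene Csf1 (ENSMUSG00000014599, chromosome 3, 107741048 to 107760469) stood at 30.7 ± 9.38 CPM in Control, 98.1 ± 31 with CSF1Ri and 74.9 ± 19.2 with the combination. The log2 differences from Control were 1.68 ± 0.31 (SE, edgeR adjusted p = 0.0917) and 1.29 ± 0.31 (adjusted p = 0.0827), neither of which passed the test. Cd40, the receptor bound by the antibody (ENSMUSG00000017652, chromosome 2, 165055627 to 165072948), stood at 130 ± 28.1 CPM in Control, 116 ± 15.4 with the CD40 agonist, 77 ± 27.4 with CSF1Ri and 244 ± 57.3 with the combination. Of these values only the rise of Cd40 from CSF1Ri to the combination passed the test (log2 fold change 1.66 ± 0.27, adjusted p = 0.0181).

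**Figure D1:**
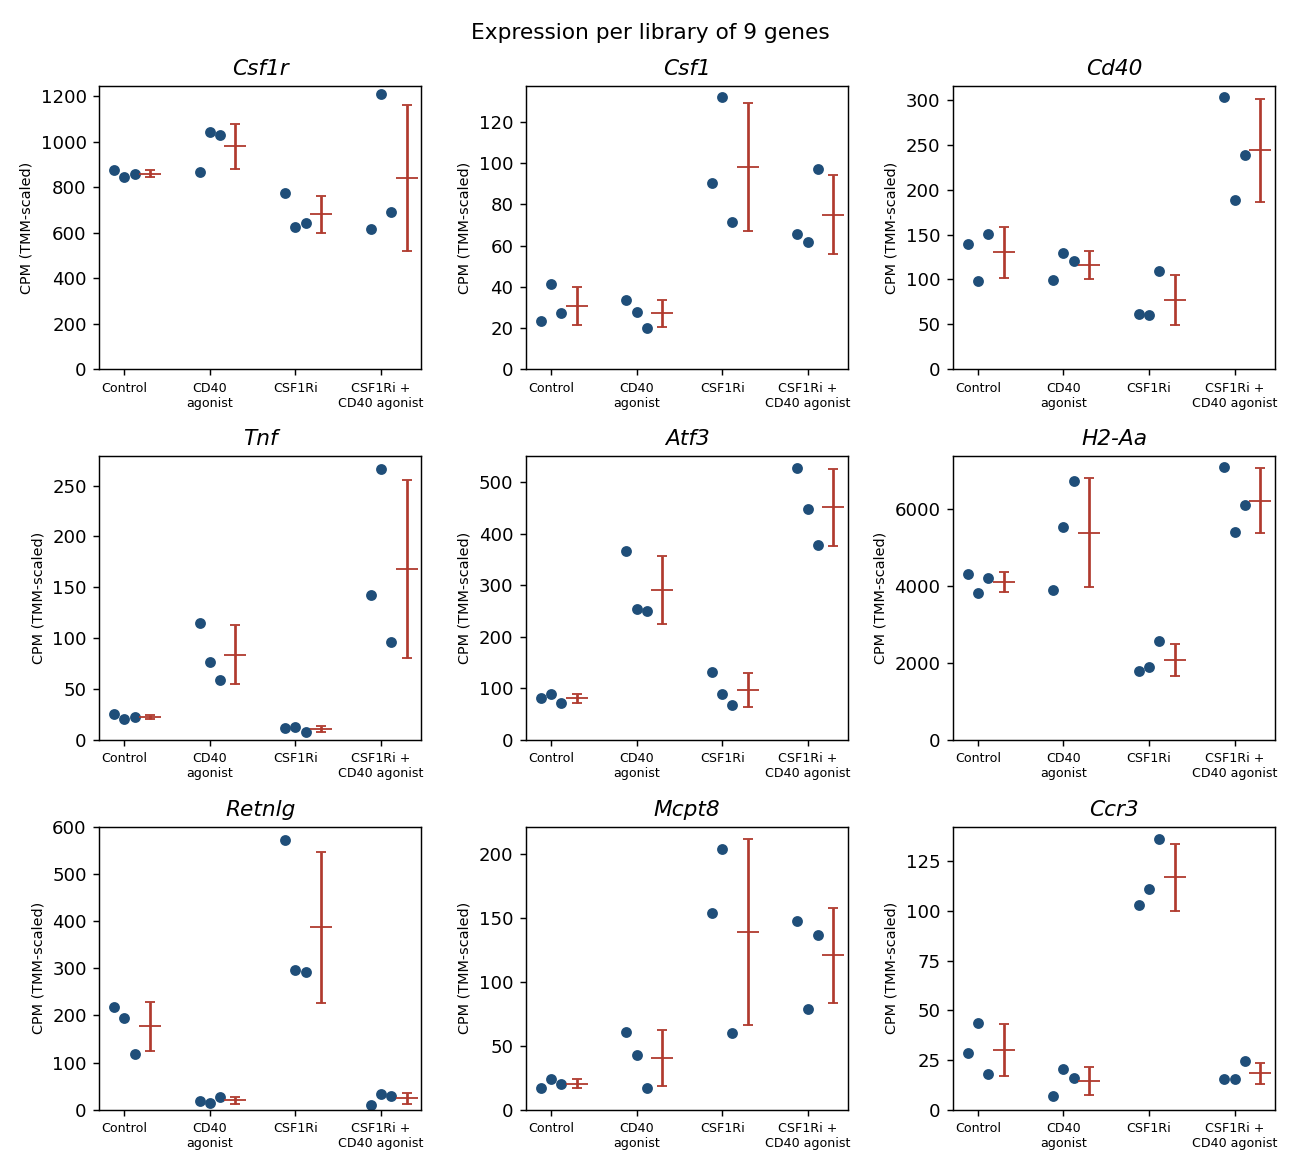
CPM of 9 genes in each of the 12 libraries by group. Points are libraries and bars are group means with their SD. Tnf lies at a mean of 168 CPM in the combination and 10.2 CPM with CSF1Ri, and Ccr3 at 18.4 CPM in the combination and 117 CPM with CSF1Ri.

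The first comparison asked what the CD40 agonist alone did. Genes of the early response to stimulation stood higher than in Control. Atf3, a transcription factor induced by stress and cytokines (ENSMUSG00000026628, chromosome 1, 191170296 to 191218039), was at 290 ± 66.5 CPM against 79.9 ± 8.89 in Control (log2 fold change 1.86 ± 0.25, adjusted p = 0.106). Tnf, the inflammatory cytokine (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007), was at 83.5 ± 28.9 CPM against 22.3 ± 2.15 (1.91 ± 0.38, adjusted p = 0.236). Retnlg, a gene of neutrophils (ENSMUSG00000022651, chromosome 16, 48872621 to 48874496), was at 20.4 ± 7.22 CPM against 177 ± 51.5 (-3.12 ± 0.47, adjusted p = 0.116). None of these passed the test. edgeR called 0 of 16027 genes, with 1231 at an unadjusted p below 0.05 where chance gives 801. DESeq2 called 195, its test at the submitters' threshold 32, limma voom 28, bias-adjusted edgeR 10 and edgeR on only the 6 libraries 43.

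Among the lists, camera with its preset correlation called 13 of 31, and 0 of them held with an estimated correlation. Dissociation and stress genes were higher, with 15 of 18 positive, a median of 0.35 and adjusted p = 4.96e-05 (adjusted p = 0.336 with an estimated correlation). Adjusted over the list alone 7 members, Atf3, Junb, Jun, Fos, Fosb, Egr2 and Ier2, rose, and 0 over all genes. Chemokines were higher in 16 of 20 members (median 1.02, adjusted p = 0.00152, and 0.336 with an estimated correlation), among them Ccl3 at 344 ± 111 CPM against 144 ± 29.8. Cell cycle genes were higher in 20 of 23 (median 1.02, adjusted p = 0.000116, and 0.336 with an estimated correlation). Type I interferon response genes were lower in 22 of 24 (median -0.89, adjusted p = 4.42e-07, and 0.434 with an estimated correlation), with Ifit3, an interferon-induced antiviral gene, at 17.4 ± 2.4 CPM against 54.8 ± 7.02. MHC class II genes (median 0.36, adjusted p = 0.00427), inflammatory cytokines (median 0.33, adjusted p = 0.0489), alternative activation genes (median 0.54, adjusted p = 0.0371) and mitochondrially encoded genes (median 0.31, adjusted p = 0.00024) were also called higher. These gave adjusted p = 0.443, 0.625, 0.453 and 0.434 with an estimated correlation. Moving with them were markers of other cell types: melanocyte and melanoma markers (median 1.66, adjusted p = 0.00506), NK cell markers (median 0.62, adjusted p = 0.00241) and endothelial markers (median 0.47, adjusted p = 0.0489) were higher. Lower were erythroid markers (median -1.81, adjusted p = 0.00427) and muscle and adipocyte markers (median -0.68, adjusted p = 0.0139). The 5 gave adjusted p = 0.434, 0.434, 0.336, 0.434 and 0.336 with an estimated correlation. Some of these calls ended when 1 library was left out. That of inflammatory cytokines ended without Control replicates 2 (adjusted p = 0.178) and 3 (0.0682), CD40 agonist replicates 2 (0.276) and 3 (0.0589) and combination replicates 1 (0.0549) and 2 (0.0537). Alternative activation genes lost theirs without Control replicates 2 (0.0646) and 3 (0.132) and CD40 agonist replicate 2 (0.281), and MHC class II genes without CD40 agonist replicate 3 (0.186). NK cell markers lost theirs without Control replicate 2 (0.0666, with the mean going from 0.66 to 0.36) and CD40 agonist replicate 2 (0.0888). Without Control replicate 3 (0.0682 and 0.157) and CD40 agonist replicate 3 (0.113 and 0.177) the endothelial and the muscle and adipocyte calls ended, and without CD40 agonist replicate 1 the endothelial one (0.251). Library CD40 agonist replicate 1 stood apart from its group (-116.4 on the third component against -12.8 and 3.7). The gene count was 0 without it, 7 without CSF1Ri replicate 3, 5 without combination replicate 2 and 1 without CSF1Ri replicate 1.

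CSF1Ri alone was compared with Control for the effect of the chow. The clearest group was that of mast cell and eosinophil markers, higher in 10 of 11 measured genes (median 1.96, mean 1.54). Mcpt8, a basophil protease (ENSMUSG00000022157, chromosome 14, 56082166 to 56085273), was at 139 ± 72.8 CPM against 20.3 ± 3.5. Ccr3, an eosinophil chemokine receptor (ENSMUSG00000035448, chromosome 9, 124021972 to 124031689), was at 117 ± 16.9 against 30 ± 13, and Ear6, an eosinophil ribonuclease (ENSMUSG00000062148, chromosome 14, 51853699 to 51854643), at 18.6 ± 14.2 against 2.43 ± 0.607. The list rose by camera (adjusted p = 4.6e-07, and 0.0344 with an estimated correlation) and by fry (adjusted p = 0.0137), the 1 list of this comparison that held under all 3. Adjusted over the list alone 7 members rose, Ear6, Mcpt8, Ccr3, Cpa3, Fcer1a, Il5ra and Mcpt4, and 0 over all genes.

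Antigen presentation and lymphocyte genes stood lower with CSF1Ri. MHC class II genes were lower in 10 of 11 members (median -0.65, adjusted p = 9.32e-05, and 0.323 with an estimated correlation), 6 of them adjusted over the list alone. H2-Aa (ENSMUSG00000036594, chromosome 17, 34282744 to 34287823) was at 2070 ± 420 CPM against 4110 ± 264. Macrophage identity and complement genes were lower in 15 of 22 (median -0.27, adjusted p = 0.0206, and 0.298 with an estimated correlation), among them Aif1 at 93.2 ± 27.1 CPM against 203 ± 19.3. Lysosome and lipid genes were lower (median -0.27, adjusted p = 0.0278, and 0.385 with an estimated correlation), with the scavenger receptor Cd36 at 81.7 ± 37.3 CPM against 308 ± 32.5. Type I interferon genes (median -0.35, adjusted p = 0.00565) and mitochondrially encoded genes (median -0.35, adjusted p = 0.000338) were lower, and glycolysis and hypoxia genes higher (median 0.28, adjusted p = 0.000954). In that order they gave adjusted p = 0.558, 0.418 and 0.323 with an estimated correlation. The same libraries held less of the lymphocyte markers, of NK cells (median -0.81, adjusted p = 9.32e-05), T cells (median -1.09, adjusted p = 0.00127) and B cells (median -1.21, adjusted p = 0.00203). Lower too were markers of fibroblasts (median -0.46, adjusted p = 0.00686), keratinocytes (median -0.88, adjusted p = 0.0278) and muscle and adipocytes (median -1.28, adjusted p = 0.0278), and neutrophil markers were called higher (median 1.28, mean 0.40, adjusted p = 0.0249). These 7 lists gave adjusted p = 0.323, 0.323, 0.298, 0.336, 0.533, 0.298 and 0.533 with an estimated correlation. Without CSF1Ri replicate 3 the calls of type I interferon genes (adjusted p = 0.153), macrophage identity (0.19), lysosome and lipid (0.123), keratinocyte (0.0579) and muscle markers (0.0988) ended. Without CSF1Ri replicate 1 those of neutrophil (0.494), fibroblast (0.108), keratinocyte (0.117) and muscle markers (0.108) ended. A Control library did the same for lysosome and lipid genes (0.0618 and 0.0516 without replicates 1 and 2), keratinocyte markers (0.154 without replicate 2), neutrophil markers (0.128 without replicate 3) and muscle markers (0.215 without replicate 3), and combination replicate 2 for muscle markers (0.0503). The mean of the neutrophil list turned to -0.42 without CSF1Ri replicate 1, and was 0.12 without Control replicate 3 and 1.09 without CSF1Ri replicate 3, so its direction rests on single libraries. The type I interferon mean went from -0.54 to -0.27 without CSF1Ri replicate 3. The monocyte list was not called (median 0.55, adjusted p = 0.264), with 5 members higher and 3 lower adjusted over the list alone. Cd300e, a receptor of patrolling monocytes (ENSMUSG00000048498, chromosome 11, 115051917 to 115062177), was at 44.2 ± 14.2 CPM against 171 ± 14.6 (-1.95 ± 0.26, adjusted p = 0.0565).

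edgeR called 2 genes in this comparison, both higher, with 1517 at an unadjusted p below 0.05. Both lie outside the naming rule and were chosen after their values were seen. Gm9973, a transcribed pseudogene (ENSMUSG00000113175, chromosome 13, 4350397 to 4391265), rose from 146 ± 18.4 CPM in Control to 428 ± 99.7 (log2 fold change 1.55 ± 0.19, adjusted p = 0.0437). Gpld1, which encodes a phospholipase (ENSMUSG00000021340, chromosome 13, 24943152 to 24992501), had 0 counts in the 3 Control libraries and 10.5 ± 6.11 CPM with CSF1Ri, at least 330-fold higher against the floor of 0.0318 CPM over the Control group. It stood at 4.12 ± 1.79 CPM with the CD40 agonist and 4.31 ± 1.94 with the combination, so Control is the group that stands apart. The count was 0 without any 1 Control or CD40 agonist library, CSF1Ri replicate 2, or combination replicate 1 or 3. It was 1 without CSF1Ri replicate 1, with neither of these genes kept, 10 without combination replicate 2, 124 without CSF1Ri replicate 3 and 338 without both outlying libraries. DESeq2 called 408, its test at the submitters' threshold 64, limma voom 23 and edgeR on only the 6 libraries 0.

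The combination was compared with Control for the joint effect of both agents. Inflammatory genes rose: Tnf reached 168 ± 87.6 CPM (log2 fold change 2.91 ± 0.39, edgeR adjusted p = 0.0156), and Tnfaip3, an inhibitor of NF-kB signalling that is also its target, rose from 92.6 ± 26.6 to 581 ± 148 CPM (2.65 ± 0.34, adjusted p = 0.0145). Atf3 rose to 451 ± 75.1 CPM (2.49 ± 0.26, adjusted p = 0.0142) and Cd69, an early activation marker, from 44.9 ± 14.7 to 247 ± 37.1 CPM (2.46 ± 0.29, adjusted p = 0.0142). Among the genes that fell, Ace, angiotensin-converting enzyme, went from 288 ± 1.45 to 62.3 ± 26.4 CPM (-2.21 ± 0.32, adjusted p = 0.0196), Cd300e to 58.2 ± 13.5 CPM (-1.56 ± 0.25, adjusted p = 0.0256) and Retnlg to 24.2 ± 11.9 CPM (-2.87 ± 0.46, adjusted p = 0.0228). The other rises of largest size were Tnfsf9 (2.68), Gbp2b (2.61), Mcpt8 (2.58) and Csprs (2.45), and the other falls Pou2f2 (-1.87), S1pr5 (-1.75), Zfyve9 (-1.61), Spic (-1.60) and Bcl2 (-1.48). edgeR called 124 genes, 74 higher and 50 lower.

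Of the inflammatory cytokines and mediators 19 of 20 were higher (median 1.26, camera adjusted p = 2.72e-06, and 0.243 with an estimated correlation). Tnf, Il6 (1.95 ± 0.32) and Osm (2.43 ± 0.40), which encode cytokines, rose over all genes, and 6 members adjusted over the list alone. NF-kB pathway genes were higher in 19 of 22 (median 0.45, adjusted p = 0.000211, and 0.198 with an estimated correlation). Tnfaip3, Nfkbia (1.91 ± 0.29) and Nfkbiz (1.41 ± 0.26), feedback regulators, rose and Nfkb1 fell (-0.65 ± 0.12) over all genes, against 8 rises and 1 fall adjusted over the list alone. Of 20 chemokines Ccl3 (1.94 ± 0.33) and Ccl4 (2.20 ± 0.40) rose, and 5 adjusted over the list alone (median 1.0, adjusted p = 0.00275, and 0.243 with an estimated correlation). Dissociation and stress genes were higher in 15 of 18 (median 0.88, adjusted p = 1.85e-07, and 0.198 with an estimated correlation). Atf3, Junb (1.29 ± 0.16), Jun (1.01 ± 0.14), Fosb (1.37 ± 0.25) and Fos rose, and 11 adjusted over the list alone. The digestion of the tumors can itself induce these genes, which were higher beside the cytokines. Interferon gamma response genes were higher in 22 of 24 (median 1.07, adjusted p = 1.44e-06, and 0.243 with an estimated correlation), with 0 rises over all genes and 13 adjusted over the list alone. Iigp1 of that list was at 1670 CPM in combination replicate 2 and at 112 and 198 in replicates 1 and 3. Without replicate 2 the list's mean went from 1.11 to 0.60 (adjusted p = 0.004). Type I interferon genes had a mean log2 CPM of 5 in the combination against 5.12 in Control.

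All 18 MHC class I genes were higher (median 0.61, adjusted p = 4.27e-07, and 0.243 with an estimated correlation), of which H2-K1 rose over all genes (0.66 ± 0.11) and 11 adjusted over the list alone. MHC class II genes were higher in 11 of 11 (median 0.43, adjusted p = 0.000379, and 0.243 with an estimated correlation), with 0 rises over all genes and 3 adjusted over the list alone. Glycolysis and hypoxia genes were higher in 18 of 20 (median 0.51, adjusted p = 1.33e-06, and 0.218 with an estimated correlation). Ldha (0.80 ± 0.13), Gapdh (0.77 ± 0.13), Aldoa (0.77 ± 0.14) and Pgk1 (0.83 ± 0.16), enzymes of glycolysis, rose, and 8 adjusted over the list alone. All 23 cell cycle genes were higher (median 1.43, adjusted p = 1.49e-07, and 0.198 with an estimated correlation), 0 over all genes and 10 adjusted over the list alone. Their mean log2 CPM was 4.75, 3 and 4.16 in combination replicates 1, 2 and 3, and that of melanocyte and melanoma markers 3.54, -0.7 and 1.57. Both lists also ranked the libraries alike within Control and the CD40 agonist, and in reverse within CSF1Ri. Which cells carried the cell cycle genes was not tested. Co-stimulation and checkpoint ligands were higher (median 0.37, adjusted p = 0.0282, and 0.243 with an estimated correlation). Tnfsf9, the ligand of the T cell receptor 4-1BB, rose from 13.6 ± 3.8 to 87 ± 36.8 CPM. The macrophage identity list was not called (median 0.05, adjusted p = 0.363), and its member Cx3cr1, a receptor of patrolling monocytes, fell (-0.71 ± 0.14). Pattern recognition genes (median 0.26, adjusted p = 0.119), the CSF1 receptor and CD40 axis (median 0.20, adjusted p = 0.148) and lysosome and lipid genes (median -0.06, adjusted p = 0.764) were not called.

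Markers of other cells moved with these groups. Melanocyte and melanoma markers (median 3.03, adjusted p = 0.0254) and neutrophil markers (median 1.01, adjusted p = 0.0445) were higher, and T cell (median -0.50, adjusted p = 0.011), B cell (median -1.23, adjusted p = 0.00207) and erythroid markers (median -1.83, adjusted p = 0.000472) lower. With an estimated correlation these gave adjusted p = 0.464, 0.518, 0.243, 0.198 and 0.243. The neutrophil call ended without Control replicate 3 (adjusted p = 0.143), CD40 agonist replicate 2 (0.0552) and combination replicates 2 (0.195) and 3 (0.156), and the melanocyte call without Control replicate 3 (0.0662) and combination replicate 1 (0.552). The melanocyte mean went from 1.40 to 0.36 without combination replicate 1, and combination replicate 2 (-0.70 as a mean log2 CPM) lay below the Control libraries (-0.29 to 0.40). The erythroid mean went from -2.86 to -1.47 without combination replicate 3 (adjusted p = 0.00042). The T cell call ended without Control replicate 3 (0.051) and combination replicate 2 (0.104). The call of co-stimulation ligands ended without Control replicate 2 (0.0611) and combination replicate 3 (0.0656). Single members that passed over all genes included Ms4a1, the B cell antigen CD20, which fell (-3.79 ± 0.74), and the mast cell and basophil genes Cpa3 (2.16 ± 0.39), Fcer1a (1.86 ± 0.34) and Mcpt8, which rose. With any 1 Control library left out, 0, 1 and 0 genes were called for replicates 1, 2 and 3, so 0 of the 124 calls held against every library left out. Atf3, Tnf, Tnfaip3, Cd69 and Ace held in 9 of 12 such fits, and Ms4a1, Bcl2 and Pgk1 in 1. The count was 49 and 77 without CD40 agonist replicates 2 and 3, 70 and 57 without combination replicates 1 and 3, 77 and 52 without CSF1Ri replicates 1 and 2. It was 232 without both outlying libraries, 5 with only the 6 libraries in the fit, 933 by DESeq2 (which called all 124), 75 at the submitters' threshold, 282 by bias-adjusted edgeR and 223 by limma voom.

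**Figure D2:**
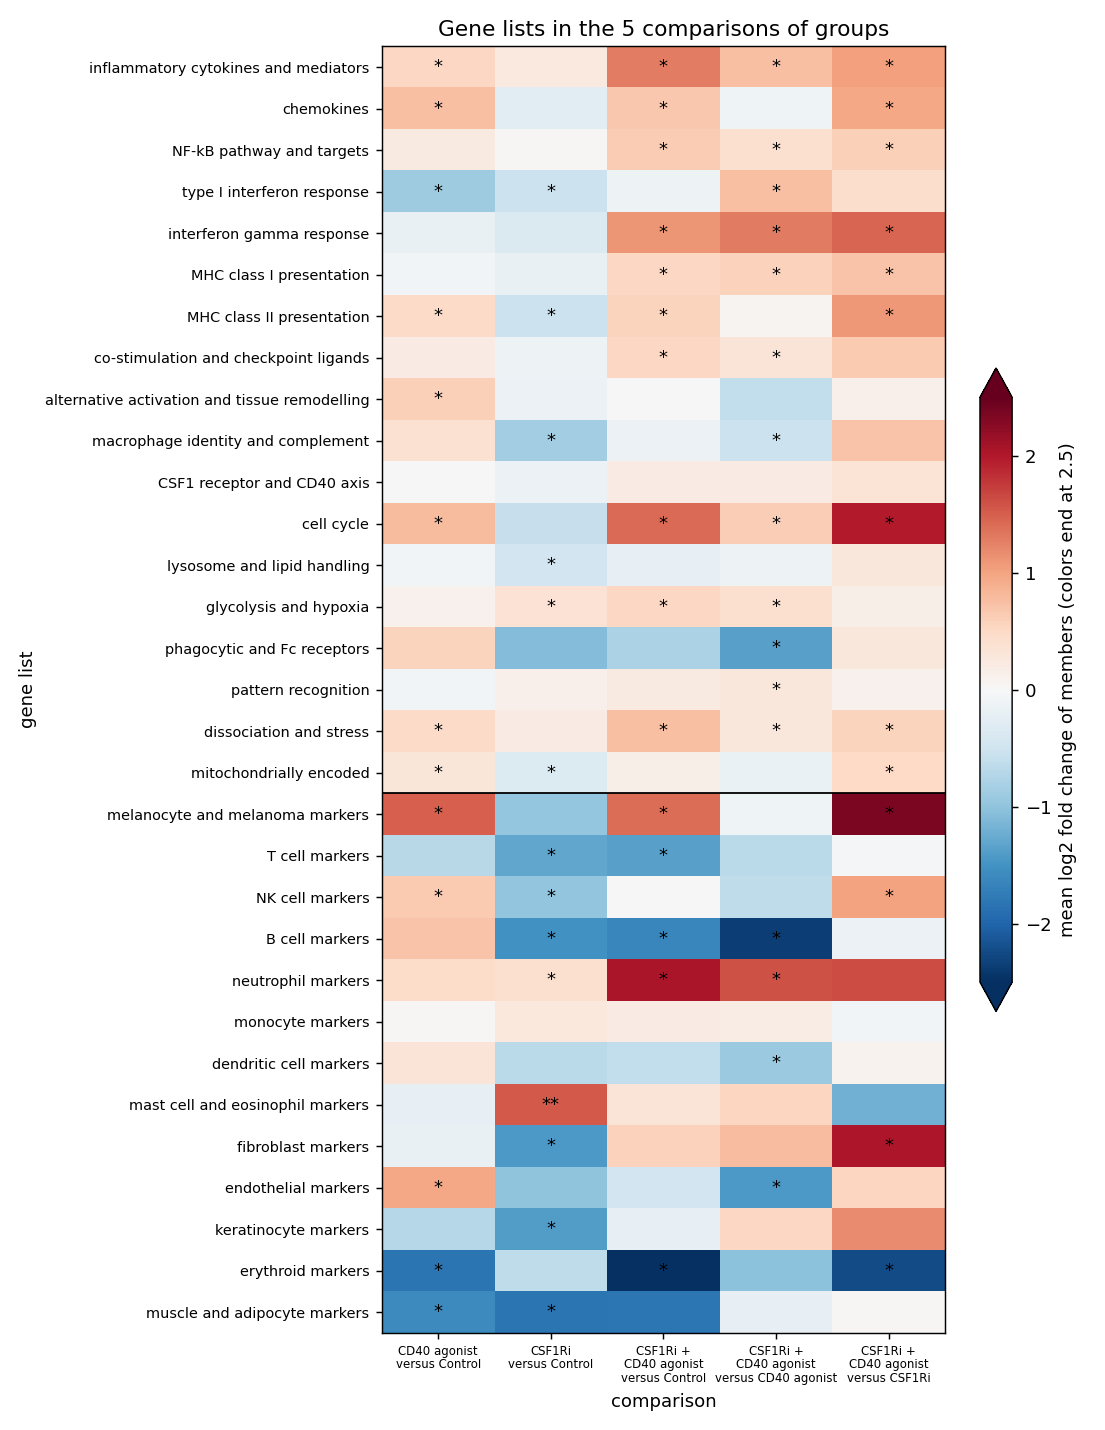
Mean log2 fold change (color, ends at 2.5) of the members of 18 pathway lists and, under the line, 13 lists of other cell types in 5 comparisons. A single star marks camera adjusted p below 0.05 with the preset correlation and a pair of stars the same also with an estimated correlation. The pair of stars stands at the mast cell and eosinophil markers with CSF1Ri, at a mean of 1.54.

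The combination was set against the CD40 agonist to ask what CSF1Ri added to the antibody. Interferon and class I genes stood higher than with the CD40 agonist. Type I interferon genes had a mean log2 CPM of 5.12 in Control, 4.24 with the CD40 agonist and 5 in the combination. Their mean was thus not raised above Control. Interferon gamma response genes stood at 5.52, 5.33 and 6.62 in the same order, and MHC class I genes at 8.22, 8.16 and 8.74. Interferon gamma response genes were higher in 22 of 24 (median 1.60, adjusted p = 7.55e-13, and 0.194 with an estimated correlation), 17 of them adjusted over the list alone. The transcription factor Irf1 stood at 413 ± 132 CPM against 204 ± 15.8 (log2 fold change 1.02 ± 0.23), and at 348 ± 34 in Control. Type I interferon genes were higher in 22 of 24 (median 0.89, adjusted p = 1.65e-06, and 0.268 with an estimated correlation), 9 adjusted over the list alone, and all 18 MHC class I genes (median 0.61, adjusted p = 2.32e-10, and 0.197 with an estimated correlation), 12 adjusted over the list alone. No single gene passed over all genes: edgeR called 0 of 16027, with 1450 at an unadjusted p below 0.05. DESeq2 called 275, its test at the submitters' threshold 22, bias-adjusted edgeR 14 and limma voom 1.

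Inflammatory cytokines (median 0.69, adjusted p = 0.000198), NF-kB genes (median 0.57, adjusted p = 0.00038), cell cycle genes (median 0.55, adjusted p = 0.00661), glycolysis and hypoxia genes (median 0.45, adjusted p = 2.78e-06), dissociation and stress genes (median 0.29, adjusted p = 0.00449), co-stimulation ligands (median 0.40, adjusted p = 0.0387) and pattern recognition genes (median 0.41, adjusted p = 0.0266) were also higher. In that order they gave adjusted p = 0.268, 0.194, 0.343, 0.197, 0.268, 0.223 and 0.534 with an estimated correlation. Nfkb2, a subunit of the non-canonical NF-kB pathway, was at 78.8 ± 4.08 CPM against 46.1 ± 3.93 (0.77 ± 0.13, adjusted p = 0.173). Phagocytic and Fc receptors (median -0.54, adjusted p = 0.00114, and 0.109 with an estimated correlation) and macrophage identity genes (median -0.32, adjusted p = 0.0357, and 0.197 with an estimated correlation) were lower. B cell markers were lower in 9 of 9 members (median -2.85, adjusted p = 9.36e-07, and 0.0807 with an estimated correlation), 5 of them adjusted over the list alone, with Ms4a1 at 0.28 ± 0.148 CPM against 9.43 ± 4.55. Endothelial (median -1.47, adjusted p = 0.00386) and dendritic cell markers (median -0.52, adjusted p = 0.0115) were lower and neutrophil markers higher (median 1.46, adjusted p = 0.00225), with adjusted p = 0.142, 0.42 and 0.343 with an estimated correlation. Combination replicate 2, which lies apart, had Irf1 at 565 CPM against 350 and 324 in replicates 1 and 3. Without it the mean of the type I interferon list went from 0.76 to 0.33 (adjusted p = 0.0203) and that of the interferon gamma list from 1.29 to 0.79 (adjusted p = 1.78e-07). Without it 6 genes were called, and 1 without combination replicate 1 or without Control replicate 2. Its omission ended the calls of pattern recognition (mean from 0.28 to 0.02, adjusted p = 0.937) and dendritic cell markers (mean from -0.93 to -0.29, adjusted p = 0.601), and took macrophage identity from a mean of -0.53 to -0.25 (0.0423). That of combination replicate 1 ended the calls of cell cycle (mean from 0.62 to 0.24, adjusted p = 0.284) and stress genes (0.0791). Without combination replicate 3 co-stimulation (0.112) and macrophage identity (0.134) were no longer called. CD40 agonist replicates ended calls of co-stimulation (0.0896 without replicate 1, 0.141 without 3), pattern recognition (0.079 and 0.063 without the same) and macrophage identity (0.154 and 0.0927 without replicates 2 and 3), and CSF1Ri replicate 3 that of co-stimulation (0.0551).

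The combination was set against CSF1Ri to ask what the antibody added, and here the most genes were called. Tnf rose from 10.2 ± 2.86 to 168 ± 87.6 CPM (log2 fold change 4.04 ± 0.41, edgeR adjusted p = 0.0066), Atf3 from 95.7 ± 32.8 to 451 ± 75.1 CPM (2.24 ± 0.25, adjusted p = 0.0066) and Il12b, a cytokine subunit that drives type 1 immunity (ENSMUSG00000004296, chromosome 11, 44400063 to 44414033), from 6.41 ± 3.79 to 141 ± 107 CPM (4.45 ± 0.88, adjusted p = 0.0337). Antigen presentation genes rose with them, such as H2-Aa from 2070 ± 420 to 6220 ± 850 CPM (1.58 ± 0.20, adjusted p = 0.00911). Among the genes that fell, Ccr3 went from 117 ± 16.9 to 18.4 ± 5.26 CPM (-2.66 ± 0.42, adjusted p = 0.0178) and Retnlg from 387 ± 160 to 24.2 ± 11.9 CPM (-4.0 ± 0.48, adjusted p = 0.00837). The largest rise was that of Iigp1, an interferon-induced GTPase (ENSMUSG00000054072, chromosome 18, 60376027 to 60392634; 5.80 ± 1.26, adjusted p = 0.0439), whose group mean of 659 ± 874 CPM rests on combination replicate 2. The means of Cfb (2130 CPM in replicate 2, 147 and 298 in the others) and Ly6i (1060, against 66 and 173) rest on the same library. The other rises of largest size were Cfb (4.63), Apod (4.53), Dnase1l3 (4.09), Ly6i (4.02) and Mmp12 (3.89), and the other falls G0s2 (-2.74), Cass4 (-2.35), Vamp1 (-2.29), the glucocorticoid-induced Fkbp5 (-2.27), Prkab2 (-1.90) and Rab44 (-1.71). For Apod and Dnase1l3 a low level with CSF1Ri enters the size. Apod was at 2.38 ± 2.3 CPM with CSF1Ri, 36.7 ± 20 in Control and 55.8 ± 30.1 in the combination. Dnase1l3 was at 3.58 ± 1.69, 26.6 ± 7.44 and 61.2 ± 19.2 CPM. edgeR called 311 genes, 199 higher and 112 lower.

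MHC class II genes were higher in 11 of 11 members (median 1.12, adjusted p = 1.3e-08, and 0.27 with an estimated correlation). Of these 7 rose over all genes, among them H2-Eb1 (1.78 ± 0.22), H2-Ab1 (1.28 ± 0.21) and their transcriptional activator Ciita (1.12 ± 0.20), and 10 adjusted over the list alone. All 18 MHC class I genes were higher (median 0.73, adjusted p = 1.38e-08, and 0.326 with an estimated correlation). H2-K1 (0.66 ± 0.11), B2m (0.54 ± 0.11) and the proteasome activators Psme1 (0.83 ± 0.17) and Psme2 (1.31 ± 0.23) were among 5 that rose over all genes, and 12 adjusted over the list alone. Interferon gamma response genes were higher in 22 of 24 (median 1.34, adjusted p = 3.18e-08, and 0.326 with an estimated correlation). Of these 6 rose over all genes, among them the chemokine Cxcl10 (3.07 ± 0.60) and the transcription factor Irf8 (0.77 ± 0.16), and 15 adjusted over the list alone. Cxcl10 stood at 172 CPM in combination replicate 2, at 37.4 and 44.8 in replicates 1 and 3, and at 5.22 to 12.7 in the CSF1Ri libraries. Without combination replicate 2 the list's mean went from 1.46 to 0.96 (adjusted p = 0.000131). Type I interferon genes were not called (median 0.63, adjusted p = 0.0527). All 23 cell cycle genes were higher (median 1.65, adjusted p = 1.3e-08, and 0.27 with an estimated correlation). Top2a (3.05 ± 0.55), Ccnb2 (3.25 ± 0.65), Mki67 (1.24 ± 0.25) and Birc5 (2.36 ± 0.49) rose over all genes, and 9 adjusted over the list alone.

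NF-kB genes were higher in 19 of 22 (median 0.51, adjusted p = 0.000239, and 0.27 with an estimated correlation). Of these 4 rose, among them Nfkbiz (1.51 ± 0.27), Tnfaip3 (1.74 ± 0.32) and Nfkb2 (0.69 ± 0.13), and Nfkb1 fell (-0.65 ± 0.12), against 10 rises and 1 fall adjusted over the list alone. Inflammatory cytokines were higher (median 0.46, adjusted p = 0.00358, and 0.402 with an estimated correlation), with 2 rises over all genes, Tnf and Il12b, and 2 adjusted over the list alone. Their call ended without CSF1Ri replicate 3 (mean from 1.02 to 0.47, adjusted p = 0.476) and combination replicate 2 (0.0513). Chemokines were higher (median 0.69, adjusted p = 0.00814, and 0.326 with an estimated correlation), with 3 rises over all genes, Ccl5, Cxcl10 and Cxcl11, and 7 rises and 2 falls adjusted over the list alone. Their call ended without CSF1Ri replicate 3 (0.116) and combination replicate 1 (0.0605). Dissociation and stress genes were higher (median 0.55, adjusted p = 8.73e-05, and 0.301 with an estimated correlation), with 2 rises, Jun and Atf3, and 8 adjusted over the list alone. Mitochondrially encoded genes were higher (median 0.51, adjusted p = 1.61e-05, and 0.326 with an estimated correlation), with mt-Cytb rising over all genes and 10 adjusted over the list alone. The co-stimulation list (median 0.44, adjusted p = 0.105) was not called, though Tnfsf9 (2.99 ± 0.49) and Cd40 rose. In lists without a call Aif1 (1.64 ± 0.23), Timd4 (2.69 ± 0.55), Clec4n (1.51 ± 0.23), Gapdh (0.94 ± 0.13), Pgk1 (0.77 ± 0.16) and Aldoa (0.67 ± 0.14) rose.

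Beside these groups, NK cell markers were higher (median 1.13, adjusted p = 6.98e-05, and 0.326 with an estimated correlation), with rises of Nkg7 (1.18 ± 0.22), Gzma (1.36 ± 0.28) and Klrk1 (0.90 ± 0.19). Melanocyte and melanoma markers (median 3.64, adjusted p = 0.00236) and fibroblast markers (median 1.42, adjusted p = 0.00248) were higher and erythroid markers lower (median -1.43, adjusted p = 0.00656), giving adjusted p = 0.337, 0.326 and 0.405 with an estimated correlation. Without combination replicate 1 the melanocyte list was no longer called (adjusted p = 0.0932), and without combination replicate 3 the erythroid mean went from -2.23 to -0.84 (adjusted p = 0.0376). In the mast cell and eosinophil list the eosinophil genes Ear6 (-4.49 ± 0.59), Il5ra (-5.05 ± 0.78) and Ccr3 fell, while Mcpt8 stood at 121 ± 37.1 CPM against 139 ± 72.8 (-0.20 ± 0.48). The list as a whole was not called (adjusted p = 0.0788). With each library left out in turn, only 6 of the 52 named genes called here stayed called in 12 of 12 fits: Tnf, Atf3, Jun, Retnlg, Fkbp5 and Ear6. Among the others H2-Aa and H2-Eb1 stayed called in 11, Cd40 and Ccr3 in 9, Cfb in 5, Il12b in 2, Ly6i in 1, and Iigp1 and Cxcl11 in 0. The count was 142, 160 and 150 without Control replicates 1, 2 and 3, 179 and 177 without CD40 agonist replicates 2 and 3, 97 and 162 without combination replicates 1 and 3, and 43 and 22 without CSF1Ri replicates 1 and 2. It was 632 without both outlying libraries, 0 with only the 6 libraries in the fit, 1484 by DESeq2 (309 of the 311 among them), 100 at the submitters' threshold and 525 by bias-adjusted edgeR.

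The comparisons of the combination with Control and with CSF1Ri called 63 genes in common, 37 higher and 26 lower in both and 0 in opposite directions. Both use the same 3 combination libraries. In 20 simulations of unchanged groups against those libraries the largest number in common was 0, but with no changed genes there is little to share, so this does not measure what sharing libraries adds to lists of this length. Independent lists of these sizes share 0.92 higher and 0.35 lower genes. The 3 libraries cannot be split into parts of 2 or more, so part of the excess may come from sharing them.

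The interaction asked whether the effect of one agent differed when the other was given. Interferon gamma response genes differed upward in 23 of 24 (median 1.62, camera adjusted p = 3.98e-11, and 0.314 with an estimated correlation), 13 adjusted over the list alone, with Cxcl10 of smallest p (3.39 ± 0.81, adjusted p = 0.319). MHC class I genes (median 0.76, adjusted p = 9.26e-09), type I interferon genes (median 1.20, adjusted p = 1.16e-08), MHC class II genes (median 0.92, adjusted p = 0.000203), NF-kB genes (median 0.44, adjusted p = 0.0106) and cell cycle genes (median 0.76, adjusted p = 0.0033) did likewise, with 12, 5, 6, 2 and 0 members adjusted over the list alone. Their adjusted p was 0.314, 0.314, 0.384, 0.314 and 0.407 with an estimated correlation. An upward difference need not be a joint rise. Type I interferon genes had a mean log2 CPM of 5.12 in Control, 4.24 with the CD40 agonist, 4.58 with CSF1Ri and 5 in the combination. In that order MHC class II genes stood at 8.89, 9.37, 8.35 and 9.44, the combination near the CD40 agonist alone. Interferon gamma genes (5.52, 5.33, 5.16 and 6.62) and MHC class I genes (8.22, 8.16, 8.02 and 8.74) were highest in the combination. Cd40 had an interaction of 1.82 ± 0.37 (adjusted p = 0.247) and Tnf of 2.14 ± 0.52 (adjusted p = 0.334). Beside them fibroblast (median 1.17, adjusted p = 0.00129) and keratinocyte markers (median 3.05, adjusted p = 0.016) differed upward and mast cell and eosinophil markers downward (median -1.61, adjusted p = 0.0033), giving adjusted p = 0.314, 0.521 and 0.314 with an estimated correlation. Without combination replicate 2 the means went from 1.65 to 1.15 for interferon gamma genes (adjusted p = 3.91e-07) and from 1.30 to 0.87 for type I interferon genes (0.0002), the latter to 0.58 without both outlying libraries (0.00585). Cxcl10 stood at 172 CPM in that replicate and at 37.4 and 44.8 in combination replicates 1 and 3. The NF-kB call ended without combination replicate 2 (adjusted p = 0.0807) and CSF1Ri replicate 3 (0.117), and the cell cycle call without combination replicate 1 (0.101). The keratinocyte call ended without Control replicate 2 (0.0641) and combination replicates 1 (0.124) and 3 (0.136). edgeR called 0 genes for the interaction, with 1305 at an unadjusted p below 0.05. DESeq2 called 172, its test at the submitters' threshold 23, bias-adjusted edgeR 0 and limma voom 0. edgeR called 15 without CSF1Ri replicate 3, 1 without CSF1Ri replicate 1 and 66 without both outlying libraries.

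Across the 4 groups together 193 genes differed by edgeR, with 2616 at an unadjusted p below 0.05. The count was 17, 23 and 30 without Control replicates 1, 2 and 3, 107, 17 and 47 without those of the CD40 agonist, 19 and 13 without CSF1Ri replicates 1 and 2, 96 and 73 without combination replicates 1 and 3, 290 without CSF1Ri replicate 3 and 291 without combination replicate 2. It was 646 without both outlying libraries, 1671 by DESeq2, 411 by bias-adjusted edgeR and 518 by limma voom.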

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

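The tests of a wrong label or library size, of cell type shares and of heat shock genes were chosen only after the results they bear on were seen; the counts over other groupings of the libraries were chosen before.

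By the test of the interaction, 9 lists had effects of one agent that differed with the other present, as mean log2 values: NF-kB genes at 0.37, type I interferon response at 1.30, interferon gamma response at 1.65, MHC class I at 0.78, MHC class II at 0.60, cell cycle at 1.19, mast cell and eosinophil markers at -1.01, fibroblast markers at 2.21 and keratinocyte markers at 1.90. Each call rests on the preset correlation, and with an estimated one the adjusted p was 0.314 to 0.521. Of 100 groupings of the 12 libraries, 50 called as many lists for the interaction (highest other 21), so chance is not excluded for these lists. For genes the real grouping called 0, which all 100 reach whatever the data, so that count decides nothing (highest other 71). The highest other of 71 genes may reflect a structure of the samples, which includes the real groups that a regrouping mixes.

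For the pairwise comparisons, 10 splits of 6 libraries cannot give a share under 0.05. With the real grouping included, the CD40 agonist against Control had as many genes in 10 splits (0 called; highest other 0) and as many lists in 1 (13 called; highest other 4). CSF1Ri against Control had as many genes in 2 splits (2 called; highest other 3) and lists in 1 (14; highest other 12), and the combination against Control had as many genes in 1 (124 called; highest other 0) and lists in 1 (15; highest other 12). The combination against the CD40 agonist had as many genes in 10 (0 called; highest other 0) and lists in 1 (16; highest other 14), and against CSF1Ri as many genes in 1 (311 called; highest other 53) and lists in 2 (13; highest other 14). A count of 0 is reached by every split whatever the data, so both counts of 10 carry no information. Other splits called up to 14 lists with the preset correlation. Over all groups, 1 of 100 groupings, the real one, called as many as 193 genes (highest other 56), so chance is excluded for that count. Likewise 1 of 100 had as many as the 63 genes shared by the comparisons of the combination (highest other 25). Most other groupings called 0 genes over all groups and shared 0, with few calls to share. The overlap is thus not tested apart from the number of calls.

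Combination replicate 2 lay apart from its group, with Iigp1 at 1670 CPM against 112 and 198, Ly6c2, a monocyte gene, at 2530 CPM against 361 and 560, and C1qb at 8.64 CPM against 198 and 93.4. A difference in library size was argued against, since its total of 34.2 M counts lies within the range of the other libraries. For a wrong label, the 200 genes of smallest p between the combination and another group were taken without the library. The share on the combination's side was counted in it and, likewise, in each library of the other group left out in turn. A share of 62% against 9% to 16% in Control libraries argues against a Control label. A CD40 agonist label cannot be told apart by this count. The share of 57.5% lay above the CD40 agonist libraries (24.5% to 36.5%), but combination replicate 1 itself had 37%. Of the 6 genes called between the combination and the CD40 agonist without the library, 1 lay on the combination's side in it. Nor can a CSF1Ri label be told apart, since 54% lies above the CSF1Ri libraries (14% to 40%) by less than their range and below combination replicates 1 and 3 (79% and 80.5%). Single genes went both ways. Against it were Tnf at 266 CPM (7 to 12.5 in CSF1Ri libraries), Fkbp5 at 12 (47.4 to 60) and Il5ra at 0.305 (6.99 to 9.94), all among the genes called between these groups. With it went C1qb at 8.64 (3.37 to 14.5) and Apoe at 11.4 (11.4 to 39, and 122 and 76.7 in combination replicates 1 and 3). A stronger response to both agents in its pooled tumors remains open and was not tested.

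Mast cell and eosinophil markers were higher with CSF1Ri than in Control. A lower share of macrophages would raise markers of every other type if nothing else changed. B cell markers went the other way, with a mean that differed by -1.51. It lay at 0.61 to 0.84 in the CSF1Ri libraries and 1.70 to 2.56 in the Control libraries on the log2 CPM scale. That argues against a lower share as the only change. It does not exclude a lower share, since the B cell list was already called lower and B cells may fall on their own. The mean of macrophage identity genes was 6.07 with CSF1Ri and 6.93 in Control, but its members went both ways. C1qb was at 7.58 ± 6.08 CPM with CSF1Ri against 61.2 ± 8.91 in Control, and Aif1 at 93.2 ± 27.1 against 203 ± 19.3. Adgre1 was at 276 ± 25.8 against 222 ± 7.68, Itgam at 533 ± 106 against 397 ± 25.5 and Lyz2 at 21500 ± 940 against 15700 ± 1960. The list mean therefore does not measure the share of macrophages. A single deviating library was argued against, since the list's mean was 1.16, 1.79 and 1.64 without CSF1Ri replicates 1, 2 and 3. More eosinophils, basophils or mast cells in these tumors, and higher expression in the cells already there, both remain open, and the sources used here name no gate that would remove them.

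Early response genes were higher together with NF-kB targets in the combination. If digestion of the tissue were the source, the heat shock members of the list would be higher too; their median against Control was 0.36, with 4 of 6 positive and values from -0.68 to 1.15, against 1.15 for the 12 other members. Members that go both ways decide nothing, so a response to digestion and a response to the agents cannot be told apart.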

How the results depend on the processing

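Leaving out both outlying libraries, bias-adjusted edgeR, limma voom and the length offset were chosen only after the results were seen. Counts of called genes kept to within 1.5 times for CSF1Ri against Control, the combination against Control, against CSF1Ri and any difference with DESeq2 size factors (2, 120, 315, 195), no filter (3, 97, 230, 176) and the length offset (2, 122, 268, 172), where the CD40 agonist against Control, the combination against the CD40 agonist and the interaction stayed at 0. In the same order of all 7 comparisons (CD40 agonist, CSF1Ri and the combination against Control, the combination against the CD40 agonist and against CSF1Ri, the interaction, any difference), DESeq2 called 195, 408, 933, 275, 1484, 172 and 1671 genes. Without both outlying libraries edgeR called 38, 338, 232, 8, 632, 66 and 646. These libraries were picked because they lay apart from their groups, so leaving them out tends to lower the spread within groups. CD40 agonist replicate 1, which lay apart on the third component, was kept. The submitters' threshold gave 32, 64, 75, 22, 100 and 23 for all but the last, and only the 6 libraries of the compared groups 43, 0, 5, 0 and 0. Bias-adjusted edgeR called 10, 2, 282, 14, 525, 0 and 411, and limma voom 28, 23, 223, 1, 242, 0 and 518. A log2 change of at least 1 left 75 and 180 genes for the combination against Control and CSF1Ri, fewer by construction, and 29 of the 63 shared genes. For the other settings the cause was not tested. In the simulated combination against Control DESeq2 called 44 unchanged genes and edgeR 1, so part of DESeq2's larger counts may be false calls. Leaving out 1 library gave 0 to 7, 0 to 124, 0 to 154, 0 to 6, 22 to 429, 0 to 15 and 13 to 291 genes.

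The replicate number as a block called 1, 3, 59, 0, 121, 0 and 49 genes. The numbers gave little sign of pairing. Deviations of same-numbered libraries correlated at -0.061 to 0.060 (18 pairs, median 0.011, 0 over 0.1). The 36 pairs with different numbers gave -0.107 to 0.073 (median -0.002). Yet 7 of 12 libraries correlated best with their own number, though same-numbered pairs are fewer, so a weak pairing is not excluded.

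Directions turned for some values that had not been called. Csf1, CD40 agonist against Control, went to 0.10 without Control replicate 2, and to -0.35 at the other end without CD40 agonist replicate 1. Csf1r, combination against Control, went to 0.15 and 0.09 without combination replicates 1 and 3, and to -0.39 without replicate 2. Csf1r, combination against CSF1Ri, went to -0.05 without combination replicate 2 and -0.09 without both outlying libraries, and to 0.49 without combination replicate 1. For the interaction Csf1 went to 0.07 without CSF1Ri replicate 2 and -0.48 without Control replicate 2, and Csf1r to -0.25 without combination replicate 2, -0.28 without both outlying libraries, -0.08 with limma voom and 0.30 without combination replicate 1. Of the called lists, pattern recognition, combination against the CD40 agonist, had its camera direction turned without combination replicate 2 (mean 0.02, against 0.49 without replicate 1), and the mean of neutrophil markers, CSF1Ri against Control, turned to -0.42 without CSF1Ri replicate 1 while its camera direction stayed. In all, named genes kept direction and side of the threshold in 1475 values, lost the call in 684, gained one in 13 and turned in 9; lists, by camera direction, did so in 1143, 216, 0 and 1. With an estimated correlation 0, 1, 0, 0, 0 and 0 lists held in the first 6 comparisons, and with fry 0, 1, 5, 8, 12 and 0 were called. DESeq2's size factors moved the median of all genes by at most 0.0163. At this spread and depth 2-fold changes are mostly missed: the simulated combination against Control recovered 10.4% of them, and 60.6% of 8-fold changes.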

Other observations

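The tests of this part, of relations between the effects of the agents, were chosen before their results were seen; the genes named first were chosen after their values were seen.

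Among neutrophil markers, Camp, Ltf and Ngp had their highest means in the combination, with a wide spread. Camp stood at 89.1 ± 84.6 CPM (SD, n = 3) in the combination, 10.2 ± 11.6 with the CD40 agonist, 1.39 ± 2.12 in Control and 0.396 ± 0.686 with CSF1Ri, and Ltf at 173 ± 152, 19.7 ± 17.2, 3.93 ± 6.6 and 1.08 ± 1.42 CPM. Ngp stood at 414 ± 388, 54.9 ± 46.3, 6.76 ± 10.5 and 2.72 ± 4.67 CPM. Against Control the combination differed by 6.0 ± 1.76 on the log2 scale for Camp (edgeR adjusted p = 0.153), and Camp, Ltf and Ngp passed when adjusted over the neutrophil list alone (adjusted p = 0.023, 0.0244 and 0.0244). Others of the list did not follow: Retnlg fell, Mmp8 stood at 155 ± 112 CPM in the combination and 160 ± 52 with CSF1Ri, and S100a8 at 418 ± 185 and 518 ± 399.

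The complement gene C1qb stood at 7.58 ± 6.08 CPM with CSF1Ri, 61.2 ± 8.91 in Control, 192 ± 97.2 with the CD40 agonist and 100 ± 95 with the combination; the difference of CSF1Ri from Control was -3.01 ± 0.90 (adjusted p = 0.306). Combination replicate 2, at 8.64 CPM, lay within the CSF1Ri libraries (3.37 to 14.5). Adgre1, the gene of the macrophage antigen F4/80, stood at 276 ± 25.8 CPM with CSF1Ri and 222 ± 7.68 in Control. The monocyte gene Ly6c2 stood at 407 ± 102 CPM with CSF1Ri and 194 ± 28.8 in Control. Hbb-bs, a hemoglobin gene, stood at 64.4 ± 17.9 CPM with the CD40 agonist and 225 ± 50.3 in Control.

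A hypothesis was that the antibody moves the same genes with and without CSF1Ri. Its effects in these settings share no library, and across 8327 genes with a mean of at least 10 CPM they correlated at Pearson r = 0.383 (Spearman rho = 0.311, 62.7% of genes with the same sign); genes are not independent replicates. Of 100 groupings of the libraries, 2 gave as high a value with the real one included (highest other 0.387, lowest -0.457), so part of the antibody's effect may be shared between the settings. The same hypothesis for CSF1Ri with and without the antibody gave r = 0.255 (rho = 0.13, 53.4%), reached by 12 of 100 groupings (highest other 0.392, lowest -0.51), which does not stand above chance.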
